A study of Sus scrofa with 6 samples.

How the data were processed

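Small RNA libraries from denuded oocytes of prepubertal gilts were made with the QIAseq miRNA Library Kit from mirVana RNA and sequenced on a NextSeq500, per the labels' protocols and the series design. There were 6 libraries, 3 from oocytes of large follicles (LO) and 3 from oocytes of small follicles (SO), and each sample's group and replicate number came from its title. The labels call the libraries biological replicates; how many animals or oocytes stand behind each is not given in the sources used here.

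Each deposited table lists 326 mature pig miRNAs with their sequence and 1 value. The file header calls the value TPM, but in every library each value was a whole multiple of 1 step whatever the sequence length. The deposited values were therefore read as RPM, reads per 1000000 of a library total set by the authors that is larger than the listed miRNA reads. Dividing by the step gave whole reads for 100% of the values above 0, within a tolerance of 0.01 read. What else the total counts, and whether the kit's molecular identifiers were used, is not given in the sources used here, so reads were treated as reads and not as molecules. The submitters' processing notes name bcl2fastq, cutadapt, Bowtie2 2.2.2, edgeR and the pig genome build Sscrofa10.2, with no role or order. No genome was used here, and no coordinates are given because the gene table at hand is of another build.

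The recovered library totals were 575850, 461505 and 1424130 reads for LO replicates 1 to 3, and 1915218, 1918901 and 2187987 for SO replicates 1 to 3. One read was worth 1.74, 2.17 and 0.702 RPM in LO and 0.522, 0.521 and 0.457 RPM in SO, so low values are coarser in LO. A count of 0 allows up to 6.50 RPM in the shallowest library, LO replicate 2, and up to 1.37 RPM in the deepest, SO replicate 3, taking 3 reads as the limit. Replicates of a group were compared by chi-square on their reads, and the ratio of chi-square to degrees of freedom was 3.07 to 21.6, so no 2 replicates of a group agreed within sampling noise. Libraries of different groups were not compared in this way.

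The design fixed before the data were examined named edgeR on counts, with limma on log2(value + 1) in its place for normalized values. As the values are RPM, the main test was limma 3.58.1 with an intensity trend on log2(RPM + 1), in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment. Fold changes are on that scale, which understates the change of low miRNAs, and positive values are higher in LO. The SE given with a log2 fold change is that of this fit. It followed the trend with abundance and not the spread of the miRNA's own replicates. For example, miR-34c and miR-143-3p, with SDs of 2.19 and 22.6 RPM in LO, had SEs of 0.595 and 0.594. The 104 miRNAs tested passed edgeR's filterByExpr on the recovered reads, and 242 had at least 1 read. edgeR 4.0.16 (quasi-likelihood with TMM) was added on the recovered reads after the unit was known, and its leave-one-out fits likewise. The design had set the list test on log2 CPM with TMM. It was run on log2(RPM + 1), the scale of the main test, and the TMM version is an alternative.

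Lists of miRNA families, clusters and cell type markers were fixed before the data were examined: 24 lists, of which 11 had at least 3 tested members. They were tested with camera (preset correlation 0.01), with fry and an estimated correlation as alternatives. Counts of miRNAs detected, the share of the 10 most abundant miRNAs and marker shares were compared by exact two-sided permutation, whose smallest p with 3 against 3 is 0.1. Marker shares were adjusted over 7 lists. Arm balance was tested by limma on log2 of the ratio of 5p to 3p reads with 0.5 added, for precursors with a mean of at least 10 reads in each arm.

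The miRNAs named were chosen by a rule fixed before the data were examined. It takes up to 15 miRNAs per direction past FDR 0.05 with group ranges apart, filled to 10 per direction by smallest p where fewer pass, the 10 most abundant of each group, and the 3 most abundant tested members of each list. It gave 58 names, all 20 of the first part by filling. Those outside it were chosen after their values were seen: miR-9-2, miR-99a, the arm pairs, the names first given in the closing section, and miR-221, miR-222 and miR-429 as members of fixed lists. Of the 326 names, 8 share a mature sequence with another, and 18 of the 58 named miRNAs lie within 1 base of another name over the first 20 nucleotides. Reads of such names may have been shared between them.

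Alternatives covered other scalings (DESeq2 size factors, upper quartile, library size, listed miRNA reads), other tools on recovered reads (DESeq2 1.42.0, limma-voom, edgeR's exact test), filters, pseudocounts of 0.5 and 5 RPM, thresholds, leaving out the 3 most abundant miRNAs, leaving out each library and the replicate number as a block. Library size here meant the summed reads of the tested miRNAs in edgeR and of the listed miRNAs in the list test. It was not the recovered library total. The tests were checked on 20 simulated sets of 104 miRNAs drawn from these libraries' means and depths. limma recovered 17.9% of 2-fold, 78.6% of 4-fold and 98.6% of 8-fold changes with 0.0602% of unchanged miRNAs called. edgeR recovered 48.6%, 90.0% and 100% with 0.783% called. camera recovered a 2-fold shift of the let-7 list in 100% of sets and called 0.5% of unmoved lists. The simulated miRNAs were drawn independently of each other, with the same dispersion in LO and SO. These rates therefore do not cover miRNAs that shift together within a library or a larger spread among the LO libraries.

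Explanations weighed in the closing section were each given a bound before the test was run, for some after the values had been seen, and a bound counted only where it held over the whole spread of the value. For leukocytes in SO replicate 1 the bound that would have counted against them, that neither of 2 other leukocyte markers is above the other libraries by an exact test, was met. It was not applied, because those markers had only 5 reads each in that library. This choice was made after the reads were seen.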

Results

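MicroRNAs (miRNAs, short RNAs that repress messenger RNAs) were measured by small RNA sequencing in denuded pig oocytes, that is, oocytes freed of their cumulus cells. The oocytes came from prepubertal gilts and fell into 2 groups. Large-follicle oocytes (LO) were aspirated from follicles of 3 to 6 mm with a 20-gauge needle, and small-follicle oocytes (SO) from follicles under 2 mm with a 23-gauge needle. Each group had 3 libraries, which the labels call biological replicates, and the series title relates the profile to the developmental competence of the oocyte. Follicle size, aspiration needle and syringe (10 mL for LO, 5 mL for SO) differed together between the groups. Reads assigned to the 326 listed mature miRNAs numbered 17464, 7755 and 42541 in LO replicates 1 to 3 and 55230, 44964 and 50936 in SO replicates 1 to 3. All 3 LO libraries were shallower than any SO library. Listed miRNAs took 2.57% ± 0.768 of the reads behind the deposited scaling in LO and 2.52% ± 0.317 in SO (SD, n = 3 each; exact two-sided permutation p = 0.9).

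The first question was which miRNAs dominate the oocyte and whether the order depends on follicle size. miR-205, a miRNA best known from epithelia, was the most abundant in both groups, with 8618 ± 2631 reads per 1000000 (RPM) in LO and 9839 ± 861 RPM in SO (SD, n = 3 each). It held 34.0% ± 5.56 of the listed miRNA reads in LO and 39.3% ± 3.43 in SO. miR-16, a member of the miR-15 and miR-16 family that acts on cell cycle genes, followed with 3306 ± 970 RPM in LO and 3066 ± 589 RPM in SO. miR-148a-3p had 1437 ± 295 and 1648 ± 539 RPM, let-7a 1314 ± 598 and 924 ± 177 RPM, and miR-128 886 ± 252 and 1208 ± 242 RPM in LO and SO.

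The 10 most abundant miRNAs of each group made 12 names together. Besides those 5 they were let-7f, let-7c, miR-125b, miR-30a-5p, miR-103, miR-182 and miR-10b. let-7f averaged 785 ± 431 RPM in LO and 637 ± 72.1 RPM in SO, and miR-125b averaged 748 ± 229 and 709 ± 39.9 RPM. miR-30a-5p averaged 633 ± 159 RPM in LO and 793 ± 171 RPM in SO. miR-182, a sensory-lineage miRNA made with miR-183, averaged 372 ± 75.9 and 464 ± 28.9 RPM. miR-10b, encoded within the HOX gene clusters, averaged 346 ± 110 and 450 ± 58.7 RPM. The 10 most abundant miRNAs of a library held 74.4% ± 4.66 of its listed miRNA reads in LO and 78.4% ± 1.56 in SO (n = 3 each), a difference of -4.05 percentage points (exact two-sided permutation p = 0.3).

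**Figure D1:**
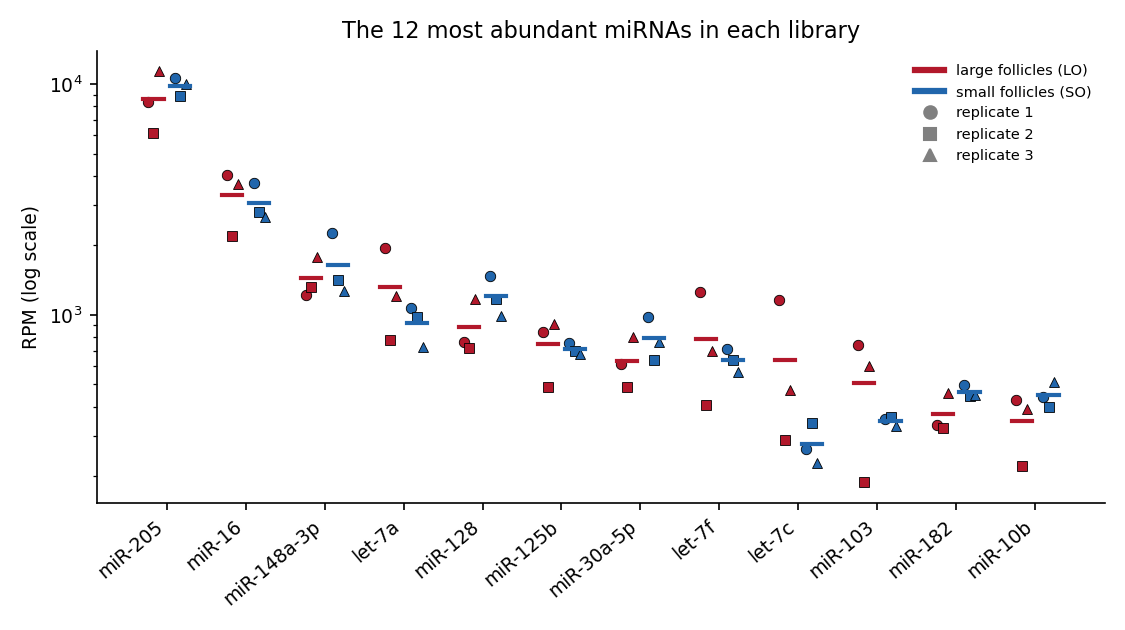
RPM (log axis) of the 12 most abundant miRNAs in each library, with LO in red, SO in blue, 1 marker shape per replicate and a bar at each group mean. miR-205 stands above every other miRNA in all 6 libraries, and let-7c and miR-103 spread widely among the LO libraries.

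The second question was how many miRNAs a library shows. At least 1 read was found for 177 ± 27.0 miRNAs in LO and 201 ± 8.19 in SO (n = 3 each), a difference of -23.7 (exact two-sided permutation p = 0.3). The LO libraries were shallower, and with every library thinned to 7755 reads the order turned, to 151 ± 3.64 miRNAs in LO and 140 ± 4.34 in SO. That difference of 10.7 had an exact permutation p of 0.1, the smallest that 3 libraries against 3 can give. At 10 RPM or more, 88.7 ± 17.6 miRNAs were found in LO and 83.0 ± 7.81 in SO (exact p = 0.6).

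**Figure D2:**
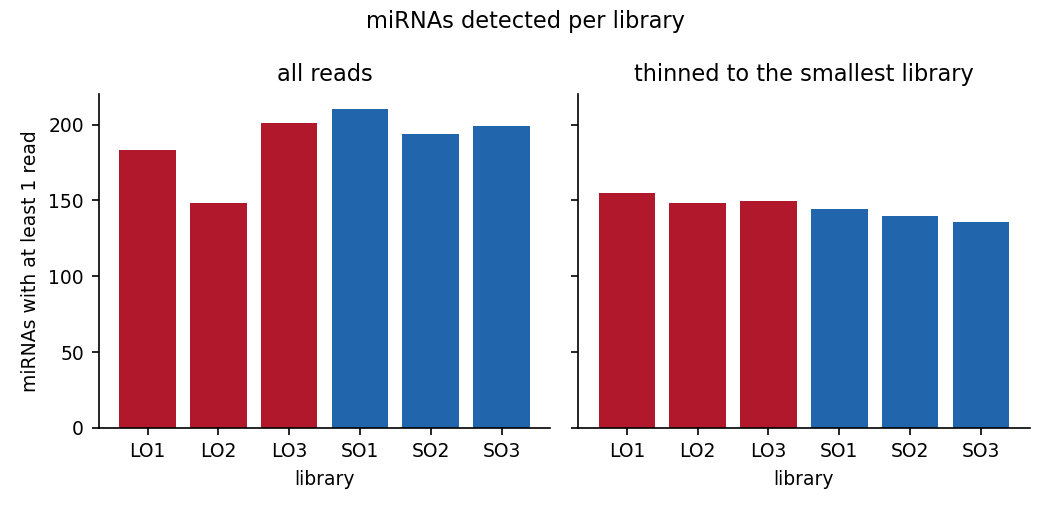
Number of miRNAs with at least 1 read in each library, with LO in red and SO in blue, from all reads on the left and with every library thinned to 7755 reads on the right. The LO libraries show 148 to 201 miRNAs from all reads; after thinning each of them lies above each SO library.

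The central comparison set LO against SO for each of the 104 miRNAs with enough reads. No miRNA passed a false discovery rate (FDR) of 0.05 by limma on log2(RPM + 1), where the smallest FDR was 0.763, and 4 had an unadjusted limma p under 0.05, all with higher means in LO. These were miR-184, miR-152, let-7c and miR-210. These 4 stayed higher in LO in each of 21 alternative settings, with a lowest log2 fold change of 0.43, for let-7c. Which other miRNAs had an unadjusted p under 0.05, and on which side, depended on the scaling. In limma scaled to listed miRNA reads 6 did, all higher in LO. In edgeR with library size only, that is, the summed reads of the tested miRNAs, 15 did, all higher in LO. With TMM, limma on log2 CPM gave 11, 4 higher and 7 lower, edgeR 13, 6 higher and 7 lower, and limma-voom 16, 5 higher and 11 lower. miR-184 averaged 106 ± 70.0 RPM in LO and 35.8 ± 4.65 RPM in SO (SD, n = 3 each), a log2 fold change of 1.35 (SE 0.55). Each SE here is limma's, set by the trend with abundance and not by the miRNA's own replicates. miR-210, the miRNA induced by hypoxia-inducible factor, averaged 45.6 ± 46.7 RPM in LO and lay at 12.5, 9.90 and 8.23 RPM in the 3 SO libraries, a log2 fold change of 1.40 (SE 0.64).

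miR-152, which shares its seed with miR-148a-3p, averaged 96.6 ± 48.7 RPM in LO and 37.9 ± 14.3 RPM in SO (log2 fold change 1.26, SE 0.55). let-7c averaged 640 ± 460 RPM in LO and 276 ± 57.1 RPM in SO (log2 fold change 0.98, SE 0.44). In LO the values of these 4 miRNAs were uneven. let-7c reached 1160 RPM in LO replicate 1, 286 RPM in replicate 2 and 473 RPM in replicate 3, and miR-210 reached 97.2, 6.50 and 33.0 RPM in the same libraries. Of the 4, miR-184 was higher in all 3 LO libraries than in any SO library, and miR-374a-3p, at 10.8 ± 5.80 RPM in LO and 4.24 ± 1.77 RPM in SO, was the other tested miRNA with that order.

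On the reads recovered from the RPM steps the number of calls depended on the tool and the scaling. edgeR with TMM, edgeR with DESeq2 size factors and edgeR's exact test each called 2, miR-184 and miR-210, and limma-voom called miR-152 and miR-184. DESeq2, run on the 242 miRNAs with at least 1 read, called 0 (smallest adjusted p 0.174). edgeR with library size only and edgeR with upper quartile scaling also called 0, with smallest FDRs of 0.0565 and 0.0501. edgeR's quasi-likelihood test with TMM scaling, a test added after the data were seen, gave an FDR of 0.0236 for miR-184 and 0.0177 for miR-210, both higher in LO. Over all 21 alternative settings the FDR of miR-184 ran from 0.00441 to 0.992 and that of miR-210 from 0.000972 to 0.992. The log2 fold change of miR-210 ran from 0.53 without LO replicate 1 to 2.38 without LO replicate 2, that of let-7c from 0.43 to 1.44 and that of miR-184 from 0.85 to 1.71 between the same settings. The edgeR count was 0 without LO replicate 1, LO replicate 3, SO replicate 1 or SO replicate 3. It was 1 (miR-210) without LO replicate 2, and 4 (let-7c, miR-152, miR-184 and miR-210) without SO replicate 2. With the replicate number as a block it was 0, with a smallest FDR of 0.371. In the limma fit, leaving out LO replicate 2 gave 18 miRNAs, all higher in LO and including let-7c, miR-152, miR-184 and miR-210.

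The remaining miRNAs added by smallest p on the side higher in LO did not pass FDR 0.05 by limma with all 6 libraries. They were let-7e (107 ± 56.7 against 55.6 ± 14.2 RPM), miR-31 (310 ± 164 against 175 ± 51.2 RPM), miR-143-3p (43.3 ± 22.6 against 22.6 ± 7.90 RPM), let-7d-5p (58.8 ± 46.6 against 27.0 ± 7.39 RPM) and miR-100 (129 ± 35.5 against 76.7 ± 15.2 RPM). Without LO replicate 2, limma called let-7e, miR-31 and let-7d-5p (FDR 0.0346, 0.0233 and 0.0346).

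On the side with lower means in LO, miR-489 had the smallest p. It averaged 23.8 ± 5.71 RPM in LO and 40.3 ± 3.71 RPM in SO, and each LO library lay below each SO library. Its log2 fold change was -0.76 (SE 0.59, limma FDR 0.780). That SE and FDR rest on the trend with abundance and not on the spread of miR-489 itself. miR-9-1 had the same order, at 8.32 ± 3.81 and 13.7 ± 2.17 RPM, but its mature sequence is identical to that of miR-9-2, at 12.2 ± 2.79 and 14.7 ± 4.21 RPM, so the 2 names cannot be separated by sequence. miR-128 gave a log2 fold change of -0.46 (SE 0.39). miR-7, a miRNA of neuroendocrine cells, averaged 219 ± 112 RPM in LO and 301 ± 66.1 RPM in SO. miR-10b, miR-146b, miR-185, miR-187, miR-190a and miR-361-3p completed the 10 names on this side, with log2 fold changes from -1.05 for miR-146b to -0.43 for miR-10b. LO replicate 2 held 0 reads of miR-146b, miR-185 and miR-361-3p, and without that library their log2 fold changes were -0.27, 0.01 and 0.25, and that of miR-190a was 0.11. Together 4 of the 104 tested miRNAs (3.85%) had group ranges that did not overlap, against the 10% that chance gives for 3 libraries against 3.

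**Figure D3:**
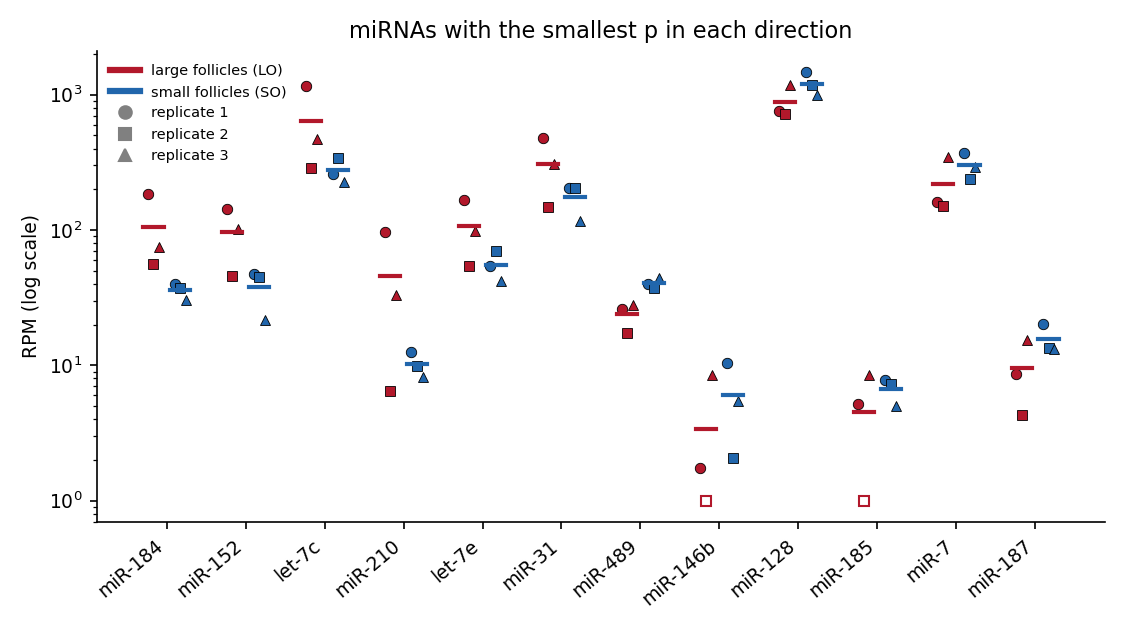
RPM (log axis) of the 6 miRNAs with the smallest p on each side of the comparison, with LO in red, SO in blue, 1 marker shape per replicate and a bar at each group mean; an open marker at 1 RPM stands for a library with 0 reads. Of these 12, only miR-184 and miR-489 keep the groups apart in every library, and LO replicate 1 is the highest library for the 6 miRNAs on the left.

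The scaling moved the balance of the profile. On the deposited scaling the median log2 fold change of the 104 miRNAs was 0.29, with 72 higher and 32 lower in LO (69.2% higher). With TMM on log2 CPM the median was 0.05 and 52.9% were higher, so changes are best read against these medians. miR-184, miR-152, let-7c and miR-210 stayed on the higher side with TMM, at log2 fold changes of 1.10, 1.01, 0.74 and 1.13. miR-16, let-7f, miR-125b, miR-92a, miR-19b, miR-27b-3p, miR-21 and miR-122 changed sign between these 2 scalings, with no call under either. Without LO replicate 1 the limma median was -0.06, and without LO replicate 2 it was 0.62.

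The next question was whether miRNA families moved together. None of the 11 lists with at least 3 tested members passed an adjusted p of 0.05 by camera, and 1 had an unadjusted p under 0.05. By limma on log2(RPM + 1) with all 6 libraries, no list member passed FDR 0.05 over all 104 miRNAs or when adjusted over the list alone. Of list members, limma-voom called miR-152, and edgeR without SO replicate 2 called let-7c and miR-152. The limma calls without LO replicate 2 included let-7c, let-7d-5p, let-7e, miR-31, miR-99a, miR-125a, miR-152 and miR-497 of these lists. In that fit the median log2 fold change of all tested miRNAs was 0.62. edgeR with TMM without the same library had a median of -0.03 and called only miR-210, which is in none of these lists. fry also called 0 lists.

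The list with the smallest p was the let-7 family, whose members accumulate as cells differentiate. All 8 tested members had higher means in LO on the deposited scaling, 6 of them above the median of all tested miRNAs, with a median log2 fold change of 0.53 (camera p = 0.0240, adjusted p = 0.264; adjusted p = 0.879 with an estimated correlation). With TMM 6 of the 8 were higher, with a median of 0.28. Without LO replicate 1 the median was 0.09, and without LO replicate 2 it was 1.01. let-7c, let-7e and let-7f each lie within 1 base of let-7a over the first 20 nucleotides, so reads may be shared among these names. The marker share of granulosa and cumulus cells was also highest in LO replicate 1, at 3.82%.

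miR-29a, miR-29b and miR-29c, a family that targets collagens and DNA methyltransferases, had log2 fold changes of 0.73, 0.40 and 0.60 (camera adjusted p = 0.583). The 4 tested members of the miR-23, miR-24 and miR-27 clusters ran from 0.24 for miR-27b-3p to 0.81, with miR-23b at 0.54 and miR-24-3p at 0.64 (adjusted p = 0.583); miR-27b-3p was at -0.00346 with TMM. In the families of miR-10, miR-99, miR-100 and miR-125, 5 of 6 members were higher, with miR-125a at 0.44 and miR-10b on the other side at -0.43 (adjusted p = 0.680). Of the miR-130, miR-301, miR-148 and miR-152 families, miR-148b-3p was at 0.43 beside miR-152 and miR-148a-3p at -0.17 (adjusted p = 0.655). These medians also moved with single LO libraries. Without LO replicate 1 they went from 0.60 to 0.19 for the miR-29 family, from 0.59 to 0.21 for the miR-23, miR-24 and miR-27 clusters, from 0.54 to 0.01 for the miR-10 to miR-125 families and from 0.43 to -0.06 for the miR-130 to miR-152 families. Without LO replicate 2 the same medians were 0.97, 1.07, 0.83 and 1.32.

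The other tested family and cluster lists had medians below that of all tested miRNAs with all 6 libraries. The miR-30 family had a median of 0.02 and a mean of -0.03, with miR-30a-5p at -0.33, miR-30d at -0.21 and miR-30e-5p at 0.42 (camera adjusted p = 0.583). The miR-17 to miR-92 cluster and its paralogs, growth-promoting miRNAs, had a median of 0.11 that turned to -0.13 with TMM, with miR-92a at 0.03, miR-20a at 0.36 and miR-19b at 0.06 (adjusted p = 0.838). The miR-15 and miR-16 family had a median of 0.13, also -0.13 with TMM, with miR-195 at 0.40 and miR-497 at 0.72 (adjusted p = 0.761). The X-linked cluster from miR-424 to miR-542 had a median of -0.25, with miR-503 at -0.52, miR-424-5p at -0.25 and miR-542-3p at 0.40 (adjusted p = 0.583). The median of this cluster was 0.07 without LO replicate 2 and 0.09 without SO replicate 1. miR-424-5p and miR-503 are also tested members of the miR-15 and miR-16 list, so these lists are not separate results. Without LO replicate 2 the medians of the miR-30, miR-17 and miR-15 lists were 0.28, 0.50 and 0.65, beside 0.62 for all tested miRNAs; without LO replicate 1 they were -0.16, -0.22 and -0.22, beside -0.06.

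**Figure D4:**
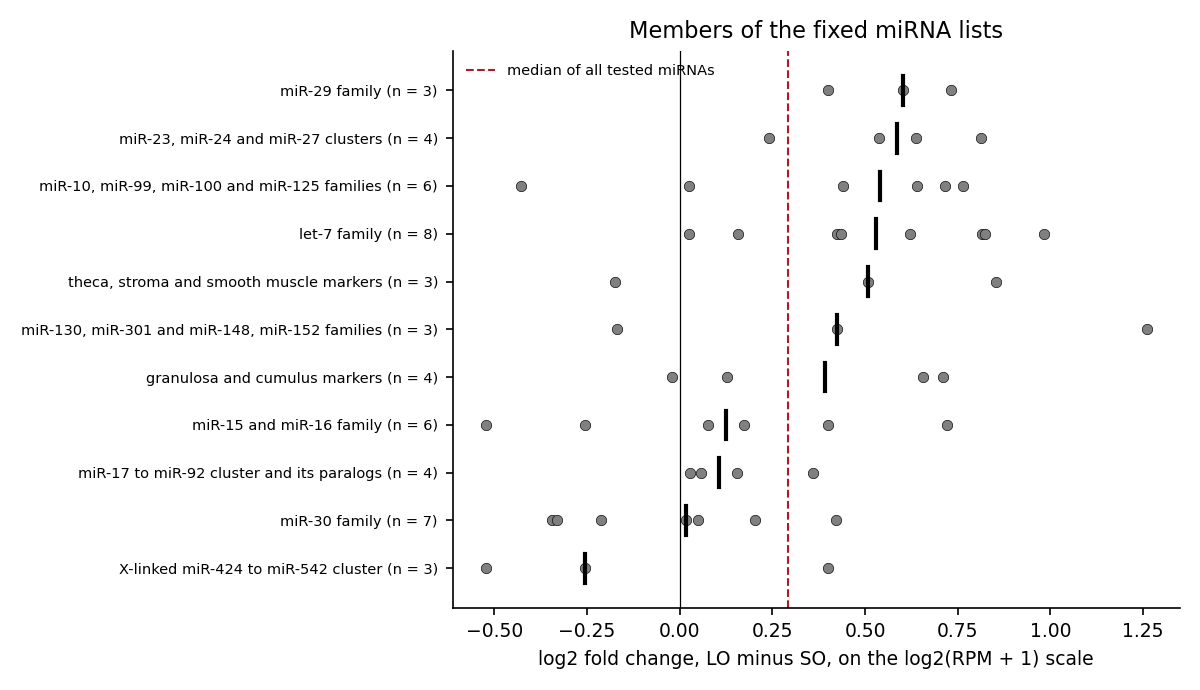
Log2 fold change, LO minus SO, of each tested member (grey points) of the 11 tested lists on the log2(RPM + 1) scale, with a black bar at each list's median and a dashed line at the median of all tested miRNAs (0.29). All 8 let-7 members lie above 0 on this scaling (6 of 8 with TMM), and the X-linked cluster has the lowest median.

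Several fixed groups were too small to test. miR-26a averaged 303 ± 91.5 RPM in LO and 246 ± 48.7 RPM in SO, and miR-181a 26.2 ± 25.3 and 11.4 ± 2.75 RPM. miR-183 averaged 66.3 ± 21.1 and 87.7 ± 13.9 RPM. miR-34c, a germ cell miRNA, averaged 28.0 ± 2.19 and 31.0 ± 8.47 RPM, beside its relative miR-34a at 26.8 ± 23.3 and 11.1 ± 3.92 RPM. miR-221 and miR-222 had 48 reads in all. Of the 20 listed miRNAs of the imprinted DLK1-DIO3 cluster, 19 had 0 reads in every library and the remaining one had 2 reads among 218890; a count of 0 in that total allows a share of up to 0.00137%. Of the 8 names fixed for the epithelial group around miR-205, only miR-205 and miR-429 were analysed here, and miR-205 alone had enough reads to test. No miRNA of the miR-302 and miR-367 cluster was analysed here.

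The fourth question was how much RNA of other cell types the libraries hold. Marker miRNAs of 7 other cell types took 3.35% ± 0.995 of listed miRNA reads in LO and 2.60% ± 0.602 in SO (n = 3 each; exact two-sided permutation p = 0.4). Granulosa and cumulus markers made up most of this, at 2.77% ± 0.960 in LO and 2.14% ± 0.436 in SO (exact p = 0.4, adjusted over 7 lists 0.56). Of their 8 listed names, 4 had enough reads to test: miR-21, miR-31, miR-202-3p and miR-202-5p. The rest had at most 10 reads each over the 6 libraries. miR-21 averaged 267 ± 157 RPM in LO and 218 ± 78.8 RPM in SO. miR-202-5p, a gonadal miRNA that oocytes also hold, averaged 159 ± 93.4 and 146 ± 60.2 RPM, so the share may include oocyte RNA. By library the share ran from 1.68% (95% exact Clopper-Pearson interval 1.57 to 1.80) in SO replicate 3 to 3.82% (3.54 to 4.11) in LO replicate 1, with LO replicate 2 at 1.93% (1.64 to 2.27). The camera test of these markers gave an adjusted p of 0.680.

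Theca, stroma and smooth muscle markers took 0.375% ± 0.107 in LO and 0.262% ± 0.0794 in SO (exact p = 0.2, adjusted 0.525), with miR-199a-3p at 23.4 ± 2.25 and 17.9 ± 10.8 RPM, miR-199b-3p at 16.7 ± 3.94 and 19.3 ± 6.89 RPM, and a camera adjusted p of 0.680 for the list. Muscle markers took 0.0558% ± 0.0223 in LO and 0.0193% ± 0.00331 in SO (exact p = 0.1, adjusted 0.525). Endothelial markers, led by miR-126-3p, took 0.0508% ± 0.0179 and 0.0313% ± 0.0176 (exact p = 0.3). Erythroid markers took 0.0190% ± 0.00606 and 0.0123% ± 0.00490 (exact p = 0.3). The liver miRNA miR-122 took 0.0420% ± 0.0211 and 0.0469% ± 0.0410 (exact p = 0.9). Leukocyte markers took 0.0417% ± 0.0199 in LO and 0.0817% ± 0.105 in SO (exact p = 0.9), and SO replicate 1 alone held 0.203% (95% exact interval 0.167 to 0.244) against 0.0157% to 0.0630% in the other 5 libraries. Intervals and limits cover counting error only.

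The last question was whether the balance between the 5p and 3p arms of a precursor differed. Of 77 precursors listed with both arms, 5 had a mean of at least 10 reads in each arm, and limma called 0 of them at FDR 0.05 and 0 at an unadjusted p under 0.05. The fit gave the 5 precursors the same SE, 0.636, so their own spreads did not enter it. No other tool was run on the arms. In miR-30a the log2 ratio of 5p to 3p reads was 4.61 ± 0.58 in LO and 5.03 ± 0.29 in SO (n = 3 each), and in miR-202 it was 3.66 ± 1.54 and 4.42 ± 0.79. In miR-423 both arms were near balance, at -0.49 ± 0.45 and -0.34 ± 0.57. miR-30e and miR-664 had FDR values of 0.763 and 0.812.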

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

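The edgeR fit with TMM, its leave-one-out and block fits, the pseudocounts, the scaling to listed miRNA reads, limma on log2 CPM with TMM and camera on log2(RPM + 1) were chosen after the data were seen, while camera on log2 CPM with TMM was fixed beforehand. Against 0 miRNAs past FDR 0.05 in limma on log2(RPM + 1), 2 were called on recovered reads by each of edgeR with TMM, edgeR with DESeq2 size factors and edgeR's exact test (miR-184 and miR-210) and by limma-voom (miR-152 and miR-184); the cause was not tested. edgeR with library size only or upper quartile scaling called 0, with smallest FDRs of 0.0565 and 0.0501. DESeq2, run on 242 miRNAs in place of 104, and the other limma settings with all 6 libraries called 0. Leaving out each library in turn gave 0 to 18 limma calls, the 18 without LO replicate 2. The number of miRNAs detected differed by 10.7 after thinning, in place of -23.7, because thinning removes the difference in depth. Lists and arm balance gave 0 calls under every alternative run, and no precursor had a mean of 50 reads in each arm, so that stricter minimum gave no value. Of 1208 values of named miRNAs under alternatives, 1089 kept their direction and side of the threshold, 99 changed sign without a call and 20 passed the threshold in the same direction; of 175 list values, 163 kept both and 12 changed direction without a call. The shallow LO libraries limit low miRNAs most: 1 read in LO replicate 2 is worth 2.17 RPM.

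Samples with the same replicate number did not deviate together (correlations of -0.34, -0.22 and 0.08, beside -0.29 to 0.43 for unlike numbers). With so few libraries this cannot tell whether equal numbers share ovaries or a collection day, which the labels do not say. With the replicate block limma called 0 miRNAs and edgeR 0 in place of 2.

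The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. limma called 0 miRNAs in the real split and at most 0 in the others (10 of 10 splits as many), camera 0 and 0 lists (10 of 10), the arm test 0 and at most 1 precursor (10 of 10), and edgeR 2 and at most 0 miRNAs (1 of 10).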

Other observations

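All tests of this part were chosen after the result was seen, except those on counting noise, GC content and identical sequences. Some abundant miRNAs fall outside the families and markers described so far, and none passed FDR 0.05 by limma with all 6 libraries. miR-146a-5p, a regulator of inflammatory signalling, averaged 169 ± 57.1 RPM in LO and 202 ± 39.6 RPM in SO (SD, n = 3 each). miR-101 averaged 141 ± 56.5 and 183 ± 63.3 RPM, and miR-335 averaged 99.4 ± 42.8 and 124 ± 30.4 RPM. miR-425-5p averaged 86.6 ± 82.0 RPM in LO and 40.9 ± 6.59 RPM in SO. Its genomic neighbour miR-191 averaged 140 ± 66.5 RPM in LO and lay at 85.6, 104 and 71.8 RPM in the 3 SO libraries. Both were highest in LO replicate 1. Without LO replicate 2, limma called miR-425-5p and edgeR with TMM did not.

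LO libraries differed more from each other than SO libraries did. The median SD over the 104 tested miRNAs was 0.73 in LO and 0.36 in SO on the log2 scale, a ratio of 2.03. Of tested miRNAs, 62.5% were highest in LO replicate 1, and 59 were lowest in LO replicate 2. Listed miRNAs took 3.03%, 1.68% and 2.99% of reads in LO replicates 1 to 3. LO replicate 2 had Pearson correlations of 0.886 and 0.936 with LO replicates 1 and 3, and 0.939 to 0.947 with the SO libraries. The marker and GC checks below were set for LO replicate 1 alone. Thinned to the depth of the shallowest library the ratio was 1.64 (1.38 to 1.98 over 20 draws). With TMM it was 1.55 (bootstrap interval over miRNAs 1.21 to 2.04). These spreads come from redrawing reads or miRNAs of the same libraries and do not measure variation between libraries. Over these spreads neither step brought the ratio down to the bound set for depth or scaling as the cause. Neither step alone therefore removed the difference in these libraries. The ratio also did not stay above the bound set against them, so each may account for part of it. In LO replicate 1 the 4 tested granulosa and cumulus markers lay 0.33 (log2) further above the other libraries than the median miRNA, at percentile 93.0 of 10000 random lists matched on expression, so carried-over follicle cells remain a possible explanation that these few markers cannot settle. The deviation of that library followed GC content with Spearman rho 0.29 across miRNAs, which are not independent replicates (permutation p = 0.00270). This was short of the bound of 0.3 set beforehand, and SO replicate 1 had a rho of -0.50. The LO libraries share 1 class of follicle size, 3 to 6 mm, so that class cannot set LO replicate 1 apart from the other LO libraries. Sizes within the class are not given per library, and their part was not tested.

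miR-142, a miRNA of blood cells, stood out in SO replicate 1. miR-142-3p had 80 reads there and 8 in the other 5 libraries together, and miR-142-5p had 22 and 3. That is 29.6 and 21.7 times as many per listed read, with the other libraries pooled. The gap to the nearest library was smaller: LO replicate 2 held 3 reads of miR-142-3p, or 6.50 RPM, against 41.8 RPM in SO replicate 1. Both arms being high argues against 1 amplified molecule, which gives reads of 1 arm, but a few amplified molecules of each arm stay possible, since reads may not be independent molecules. Leukocytes are a candidate source: of the other markers miR-150 had 5 reads against 6 (2.47 times, Fisher's exact p = 0.159) and miR-155-5p 5 against 27 (0.549 times, exact p = 0.307). Neither passed this test, which counts reads as independent, and that met the bound written against leukocytes, but 5 reads each are too few to exclude them. Of 2 immune miRNAs outside the fixed marker list, miR-342 had 43 reads against 124 (1.03 times, exact p = 0.859) and miR-146b 20 against 29 (2.04 times, exact p = 0.0198, adjusted 0.0594). Leukocytes stay open, and miR-223 was not analysed here. Of the erythroid markers, miR-451 had 5 reads against 8 (1.85 times, exact p = 0.335), miR-486 1 against 9 (0.329 times, exact p = 0.468) and miR-144 2 against 5 (1.19 times). These reads are too few to decide on red blood cells, and no other biological explanation was tested.

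Of the 4 pairs of names with identical mature sequences, 2 had at least 10 reads. miR-9-1 and miR-9-2 divided 106 to 122, within an even division (exact binomial p = 0.321), and miR-218 and miR-218-5p divided 17 to 43 (exact binomial p = 0.00107), from 2 to 0 in LO replicate 2 to 3 to 16 in LO replicate 3. The test takes each read as assigned on its own, so it argues against an even random division read by read and says nothing of identical reads assigned together.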
